A study of Homo sapiens with 12 samples.

How the data were processed

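RNA was measured in 12 libraries of the Nalm6 line, 4 WT, 4 TOP2B-/- and 4 TOP2A+/-. Per the labels' protocols, cells were grown in RPMI medium with serum and antibiotics, total RNA was extracted with a column kit, and libraries were made with a stranded mRNA kit for paired reads of 100 bp. Per the submitters' processing notes, FastQC 0.11.2 and Salmon were used, with the genome build GRCh37. The version of Salmon and the annotation release are not given in the sources used here. The authors deposited TPM per Ensembl transcript, that is, abundances that Salmon estimates from reads assigned in part to several transcripts and divides by transcript length and by the library total. TPM keeps no depth, so no test on counts was made, and the depth of each library is unknown. A value of exactly 0 can be a failed estimate, so a gene is described as listed at 0. TPM are shares of a library, so a rise of abundant transcripts lowers all others.

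Transcripts were matched by their Ensembl identifier to GENCODE release 29 on GRCh38, used for gene names, biotypes, order and gene coordinates only. In all 180930 transcripts (92.8%) were matched, which held 93.2% to 94.3% of the TPM of each library, and their TPM were summed over 52719 genes. The 14063 transcripts with no match were not assigned to genes. Groups were taken from the genotype labels and columns from the sample numbers in the titles.

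Genes with at least 1 TPM in at least 4 of the 12 libraries were tested (14555 genes). log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend), all 12 libraries in 1 fit with 9 residual degrees of freedom, and 3 contrasts were taken. p-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. For the targeted genes and the carbonyl reductases an exact two-sided permutation test over the 70 assignments of 4 libraries against 4 was added, whose smallest p is 0.0286. For genes over 100 kb, splits of all libraries of a comparison were counted beside the camera p. The 28 gene lists were written before the data were examined, and the 24 with at least 5 tested genes were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry. They covered topoisomerases and repair, carbonyl reduction and drug efflux, end joining, homologous recombination, p53 targets, G1/S, G2/M, pre-B identity, HLA, T and NK, myeloid, erythroid, fibroblast and epithelial, and neuronal markers, protocadherins, HOX genes, translocation partners, cohesin, immediate early, glucocorticoid, interferon, NF-kB, cholesterol, glycolysis, unfolded protein, NRF2, mitochondrial and ribosomal protein genes. Overlap of the calls in both mutants was set beside simulated unchanged groups against the real WT libraries, and recomputed with the WT libraries split.

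Genes named were fixed by a rule before the data were examined. TOP2A, TOP2B, TOP1, CBR1 and CBR3 were always named. For each mutant against WT the 10 higher and 10 lower protein-coding genes with the largest log2 fold change were taken, among genes past the threshold with all 4 libraries of each group apart and a mean of at least 5 TPM in the higher group, and 5 each way between the mutants. Up to 4 members with the smallest adjusted p came from each list past the threshold and from the pre-B, p53 and carbonyl lists, and 5 each way from the calls shared by both mutants. Genes outside the rule are said to be chosen after their values were seen.

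The fit was tested on simulated data. Values were drawn independently for each gene with the same spread in all libraries, and changed genes had a mean log2(TPM + 1) over 2. The simulated libraries hold no outlying library and no difference in length score, so recovery in the real TOP2B-/- libraries may differ. For TOP2B-/- against WT, over 14555 genes, 60% of 50 genes raised by 0.5 (log2) were recovered, 92% of 50 raised by 1, 98% of 50 raised by 2 and 94% of 50 lowered by 1, and 12 unchanged genes were called. Alternatives were other pseudocounts (0.1 and 5), other filters, 3 other scalings, other fits, single transcripts, and leaving out each library in turn. Leaving out TOP2B-/- replicates 2 and 4, adding the length score as a covariate, and estimating the correlation within an alternative, were chosen after seeing the data. The length score is the median log2(TPM + 1), relative to the mean library, of genes whose transcripts are over 5000 bases minus that of genes under 1000 bases, among genes of at least 5 TPM. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.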

Results

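Gene expression was measured by RNA sequencing in Nalm6, an established human B cell precursor leukaemia line, in 3 genotypes with 4 libraries each. The genotypes were the wild type (WT), cells that had lost both copies of TOP2B (TOP2B-/-) and cells with 1 functional copy of TOP2A (TOP2A+/-). TOP2A and TOP2B are the 2 human type II topoisomerases, enzymes that pass one DNA duplex through a transient double-strand break in another. They are the targets of anthracyclines and etoposide. TOP2A is the isoform of dividing cells, whereas TOP2B is expressed in dividing and resting cells. The deposited values were TPM, the share of a library that each transcript takes, for each of the 12 libraries. Each library summed to 1000000, so its sequencing depth is unknown and no counting interval was computed. The labels do not say whether the libraries of a genotype came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. Values are mean TPM ± SD of the 4 libraries of a genotype, unless a single library is named. The log2 fold changes are on the log2(TPM + 1) scale, which understates changes of weakly expressed genes.

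Between 92150 and 94722 transcripts were above 0 in the WT libraries, between 87899 and 94796 in TOP2B-/- and between 94253 and 95370 in TOP2A+/-. Libraries of the same genotype correlated across tested genes with r from 0.978 to 0.982 in WT, from 0.979 to 0.981 in TOP2A+/- and from 0.954 to 0.977 in TOP2B-/-, where genes are not independent replicates. The TOP2B-/- libraries differed in how much long transcripts contributed. A length score, the median log2 level of 892 genes with long transcripts minus that of 921 genes with short transcripts, relative to the mean of all libraries, was 0.29 and 0.22 in TOP2B-/- replicates 1 and 3 but -0.47 and -0.13 in replicates 2 and 4, against -0.08 to 0.11 in WT and -0.10 to 0.12 in TOP2A+/-. POLR2A, the large subunit of RNA polymerase II and a long transcript, had 2.57 TPM in TOP2B-/- replicate 2 and 10.4 TPM in replicate 4, against 24.0 and 25.7 TPM in replicates 1 and 3. RPL13, a short ribosomal protein transcript, had 1403 TPM in replicate 2 and 834 TPM in replicate 1. POLR2A and RPL13 were chosen after their values were seen. Principal component 1, with 22.7% of the variance, ran from -29.6 in TOP2B-/- replicate 1 to 49.0 in TOP2B-/- replicate 2. The count of genes for TOP2B-/-, and the members called in the lists that moved most, are therefore given also without replicates 2 and 4. Replicates 1 and 3, which then remain, had the 2 highest length scores of the 12 libraries, so that alternative favours long transcripts.

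**Figure D1:**
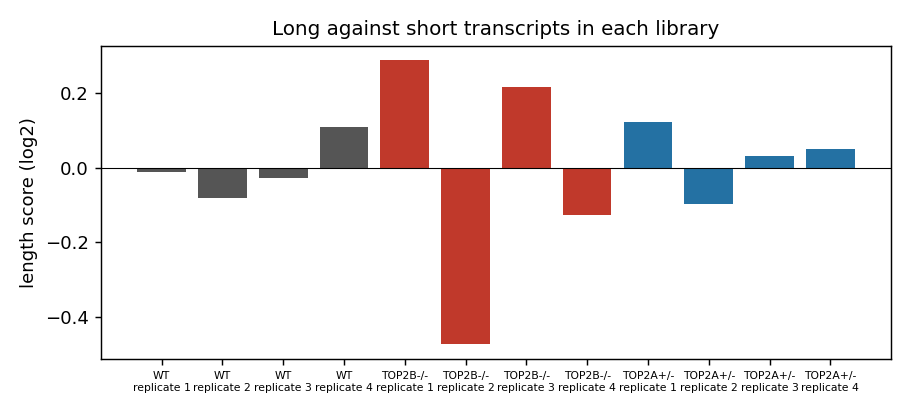
Length score of each of the 12 libraries (log2, long against short transcripts), coloured by genotype, with 1 bar per library. TOP2B-/- replicate 2 lies lowest at -0.47 and TOP2B-/- replicate 1 highest at 0.29.

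The targeted genes were examined first, since they check the genotype labels. TOP2B (ENSG00000077097, chromosome 3, 25597905 to 25664907 on the minus strand, GRCh38) fell from 268 ± 23.5 TPM in WT to 28.9 ± 10.6 TPM in TOP2B-/-, which is 10.8% of the WT level, and was 265 ± 27.3 TPM in TOP2A+/-. The 4 TOP2B-/- libraries had 29.9, 15.5, 28.96 and 41.3 TPM, against 246 to 301 TPM in the WT libraries (log2 fold change -3.24 ± 0.22 SE, adjusted p = 4.95e-06). The exact two-sided permutation p was 0.0286, the smallest that 4 libraries against 4 can give. The main protein-coding transcript, TOP2B-201, carried 14.8 ± 3.76 TPM in TOP2B-/- against 204 ± 5.39 TPM in WT. The short retained-intron transcripts TOP2B-205 and TOP2B-207 stayed near the WT level, with 3.76 ± 1.10 and 3.36 ± 1.43 TPM in TOP2B-/- against 4.42 ± 1.24 and 4.78 ± 1.21 TPM in WT.

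TOP2A (ENSG00000131747, chromosome 17, 40388516 to 40417950 on the minus strand, GRCh38) fell to 125 ± 3.66 TPM in TOP2A+/-, 60.7% of the WT level of 206 ± 7.23 TPM (log2 fold change -0.72 ± 0.10 SE, adjusted p = 0.00107; exact permutation p = 0.0286). The 4 TOP2A+/- libraries lay between 122 and 129 TPM and the 4 WT libraries between 201 and 217 TPM. Its level in TOP2B-/- was 213 ± 36.3 TPM and did not differ from WT by the test (adjusted p = 0.888). That value rests on TOP2B-/- replicate 2, which had 163 TPM against 211 to 245 TPM in the other 3 libraries. Without it the difference passed the threshold (adjusted p = 0.0462). TOP1, the type I topoisomerase, fell from 133 ± 3.19 TPM to 106 ± 12.98 TPM in TOP2B-/- (adjusted p = 0.0082) and was 127 ± 3.84 TPM in TOP2A+/- (adjusted p = 0.621, although the 4 libraries lay apart from WT, exact permutation p = 0.0286).

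CBR1 and CBR3 encode carbonyl reductases, which reduce anthracyclines to their alcohol metabolites, and the question put to them was whether their transcripts depend on the topoisomerase that these drugs target. CBR1 (ENSG00000159228, chromosome 21, 36069941 to 36073166 on the plus strand, GRCh38) was listed at 0 in all 4 TOP2B-/- libraries. It had 4.73, 4.93, 4.77 and 4.37 TPM in the WT libraries and 5.46, 6.08, 5.85 and 6.09 TPM in the TOP2A+/- libraries. The difference between TOP2B-/- and WT had an adjusted p of 8.71e-09 and an exact permutation p of 0.0286. CBR1 was the only protein-coding gene listed at 0 in all 4 TOP2B-/- libraries and at 1 TPM or more in all 4 WT libraries, among 5 genes of any type. The TOP2A+/- level was 5.87 ± 0.30 TPM against 4.70 ± 0.24 TPM in WT (adjusted p = 0.0263). That call ended when WT replicate 1, 3 or 4 or TOP2A+/- replicate 2, 3 or 4 was left out (adjusted p of 0.0613 to 0.083). It ended with either other centring of the libraries (adjusted p of 0.112 with the median log ratio and 0.253 with quantile normalization). It also ended with a pseudocount of 0.1, without a filter and with the highest transcript alone (adjusted p of 0.15, 0.092 and 0.16).

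CBR3 (chromosome 21, 36134912 to 36146566 on the plus strand, GRCh38) rose from 2.55 ± 0.39 TPM in WT to 4.60 ± 0.41 TPM in TOP2A+/- (log2 fold change 0.66 ± 0.10 SE, adjusted p = 0.00192; exact permutation p = 0.0286). In TOP2B-/- it was 3.55 ± 0.47 TPM (log2 fold change 0.36 ± 0.10 SE, adjusted p = 0.0316), a gain that was higher than WT in all 4 libraries. That call ended when WT replicate 1, 3 or 4 or TOP2B-/- replicate 2 or 4 was left out (adjusted p of 0.0502 to 0.0884) and when libraries were centred on their median log ratio (adjusted p = 0.125). Of the neighbours of CBR1, the adjacent SETD4 had 13.5 ± 3.54 TPM in TOP2B-/- and 15.2 ± 2.12 TPM in WT (adjusted p = 0.478), and RUNX1 had 45.2 ± 16.1 and 31.8 ± 3.72 TPM (adjusted p = 0.213). RCAN1 rose from 21.4 ± 0.60 to 36.3 ± 2.08 TPM in TOP2B-/- (adjusted p = 4.26e-06) and fell to 16.8 ± 0.48 TPM in TOP2A+/- (adjusted p = 0.00113). SETD4, RUNX1 and RCAN1 were chosen after their values were seen.

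**Figure D2:**
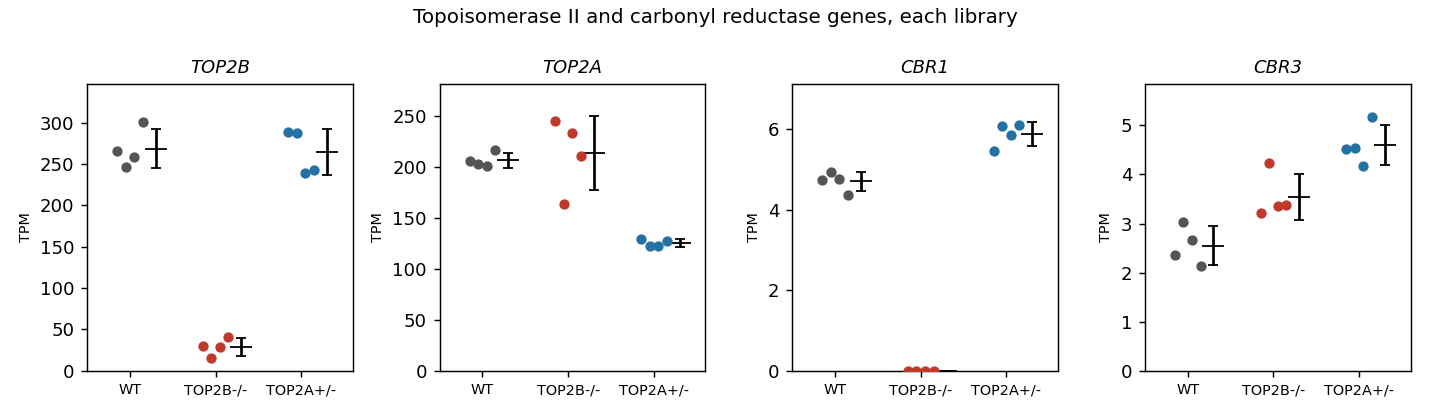
TPM of TOP2B, TOP2A, CBR1 and CBR3 in each library (points) by genotype, with the mean and SD of 4 libraries (black). CBR1 lies at 0 in all 4 TOP2B-/- libraries and between 4.37 and 6.09 TPM in the other 8.

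The comparison of TOP2B-/- with WT asked which other transcripts change when TOP2B is lost. The largest changes are taken throughout from protein-coding genes with a mean of at least 5 TPM in the higher group and all libraries apart. Among these the 4 largest increases were those of LILRB1, LGALS9, NKG7 and GZMA. LILRB1, an inhibitory receptor for HLA class I, rose from 0.83 ± 0.17 to 9.19 ± 3.37 TPM (log2 fold change 2.42 ± 0.21 SE). LGALS9, which encodes galectin-9, rose from 3.25 ± 0.34 to 20.2 ± 4.70 TPM and NKG7, which encodes a cytotoxic granule protein, from 2.89 ± 0.28 to 13.4 ± 1.01 TPM. GZMA, which encodes the serine protease granzyme A, rose from 21.2 ± 0.80 to 79.4 ± 7.34 TPM (log2 fold change 1.85 ± 0.07 SE). Large decreases after that of TOP2B were in the zinc finger genes ZSCAN18 (6.84 ± 0.88 to 0.42 ± 0.27 TPM), ZNF43 (6.98 ± 0.81 to 1.62 ± 0.62 TPM) and ZNF626 (5.08 ± 0.32 to 1.05 ± 0.23 TPM). The receptor genes GPR146 (6.01 ± 0.79 to 1.10 ± 0.45 TPM) and GPER1 (6.18 ± 0.94 to 1.45 ± 0.15 TPM) also fell. Among abundant transcripts, RPL22L1, a paralog of the ribosomal protein gene RPL22, fell from 662 ± 51.6 to 259 ± 33.7 TPM.

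LILRA2, a second receptor of the LILRB1 family, rose from 1.47 ± 0.27 to 6.74 ± 1.32 TPM. C1orf54 rose from 19.02 ± 0.59 to 53.2 ± 3.38 TPM, APOBEC3B, a cytidine deaminase, from 13.4 ± 0.42 to 36.6 ± 1.36 TPM, and SMIM24 from 3.92 ± 0.23 to 11.7 ± 1.06 TPM. ARMH1 rose from 1.49 ± 0.27 to 5.42 ± 1.40 TPM and CMPK2, an interferon-inducible nucleotide kinase, from 2.56 ± 0.23 to 7.94 ± 0.21 TPM. METRN fell from 8.64 ± 0.77 to 2.67 ± 0.43 TPM, ARMCX5 from 5.09 ± 0.67 to 1.61 ± 0.73 TPM and SPP1, which encodes the secreted phosphoprotein osteopontin, from 21.7 ± 0.81 to 8.17 ± 0.68 TPM. Adjusted p for these largest changes ran from 9.47e-08 for C1orf54 to 2.06e-05 for LILRB1 and 3.66e-05 for ZNF43, and was 0.00016 for ARMH1 and 0.000862 for ARMCX5. For each of them the 4 libraries of each genotype lay apart. LILRB1 and LILRA2, and the zinc finger genes of chromosome 19, belong to families of similar sequence, so their separate levels are uncertain.

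In all, 2784 of 14555 tested genes passed the threshold, 1868 higher and 916 lower in TOP2B-/- (67.1% higher), and 106 of them had a change of at least 2-fold, 71 higher and 35 lower. All 4 libraries of each genotype lay apart from those of the other for 21.4% of the tested genes, against 2.86% by chance. With libraries centred on their median log ratio the split became 1573 higher and 1449 lower (52.1% higher), and with quantile normalization 1514 and 1383. Without TOP2B-/- replicates 2 and 4, an alternative chosen after seeing the data, 5654 genes passed, of which 2453 were among the 2784.

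Among the gene lists, the p53 targets had 12 of 26 tested members higher in TOP2B-/- and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 7.41e-05). With an estimated correlation the adjusted p was 0.0431, but 0.112 once the length score was fitted. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 64.9 ± 2.26 to 107 ± 3.001 TPM. DDB2, a DNA damage recognition factor, rose from 35.1 ± 0.85 to 51.4 ± 1.42 TPM. BBC3, the pro-apoptotic PUMA, rose from 3.11 ± 0.18 to 6.33 ± 0.87 TPM, and CCNG1 from 96.2 ± 4.18 to 126 ± 6.90 TPM. The list of HLA class II and antigen presentation genes had 10 of 25 members higher and 0 lower (12 and 0 adjusted over the list alone; camera adjusted p = 0.000351, and adjusted p = 0.037 with an estimated correlation, but 0.112 once the length score was fitted). HLA-DRA went from 499 ± 12.7 to 622 ± 10.8 TPM, HLA-DRB1 from 51.5 ± 0.42 to 62.8 ± 0.76 TPM, HLA-DMA, which loads peptides onto class II, from 49.9 ± 1.52 to 70.8 ± 2.80 TPM, and HLA-F, a class I gene, from 13.8 ± 1.29 to 19.95 ± 0.47 TPM. HLA alleles can share reads, and their separate levels are uncertain.

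G1/S and S phase genes were higher for 11 of 27 members and lower for 0 (13 and 0 adjusted over the list alone; camera adjusted p = 7.41e-05, but adjusted p = 0.199 with an estimated correlation). CCNE2 and CCNE1, the E-type cyclins of S phase entry, rose from 92.7 ± 2.76 to 156 ± 9.34 TPM and from 20.4 ± 1.53 to 30.4 ± 1.73 TPM. RRM2, a subunit of ribonucleotide reductase, rose from 278 ± 9.50 to 409 ± 37.2 TPM, and E2F1, the transcription factor of S phase genes, from 54.4 ± 1.35 to 64.2 ± 2.42 TPM. Of the homologous recombination genes 7 of 26 were higher and 0 lower (9 and 0 adjusted over the list alone). BRIP1 rose from 25.3 ± 1.21 to 35.8 ± 6.10 TPM, RAD54B from 15.2 ± 0.86 to 20.03 ± 2.29 TPM, RBBP8, the end-resection factor CtIP, from 73.8 ± 3.46 to 86.8 ± 2.74 TPM, and RPA2 from 91.3 ± 3.25 to 104 ± 6.36 TPM. The camera adjusted p of this list was 0.0373, but adjusted p = 0.773 with an estimated correlation, and 0.0569 and 0.0857 without TOP2B-/- replicate 1 or 3. The RPA2 call ended without WT replicate 4 or TOP2B-/- replicate 4 (adjusted p of 0.0512 and 0.0525), and those of RPA2, RBBP8 and E2F1 ended with libraries centred on their median log ratio (adjusted p of 0.293, 0.131 and 0.0912).

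Cholesterol biosynthesis genes were higher for 9 of 22 members and lower for 0 (10 and 0 adjusted over the list alone; camera adjusted p = 0.00176, but adjusted p = 0.302 with an estimated correlation). FDFT1, squalene synthase, rose from 100.1 ± 4.03 to 133 ± 3.67 TPM, IDI1 from 193 ± 6.96 to 248 ± 7.60 TPM, INSIG1 from 58.3 ± 1.10 to 72.9 ± 3.28 TPM and SC5D from 25.6 ± 0.76 to 31.9 ± 3.10 TPM. Of 8 tested T and NK cell markers 5 were higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.000522, but adjusted p = 0.149 with an estimated correlation). Besides GZMA and NKG7 they included LCK, a tyrosine kinase of lymphocytes, from 8.93 ± 1.13 to 15.5 ± 3.29 TPM. They also included ZAP70, from 28.7 ± 2.22 to 41.2 ± 8.08 TPM. The ZAP70 call ended without WT replicate 1 or 2 or TOP2B-/- replicate 3 (adjusted p of 0.0528 to 0.0566).

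Glycolysis and hypoxia genes were lower in TOP2B-/- for 11 of 25 members and higher for 2 (15 and 3 adjusted over the list alone; camera adjusted p = 1.32e-06, but adjusted p = 0.199 with an estimated correlation). LDHA, lactate dehydrogenase A, fell from 999 ± 50.6 to 631 ± 80.3 TPM, and TPI1, triosephosphate isomerase, from 597 ± 13.3 to 378 ± 21.6 TPM. ENO1, enolase, fell from 964 ± 15.2 to 787 ± 20.5 TPM and BNIP3, a mitophagy receptor induced by hypoxia, from 58.6 ± 6.64 to 35.8 ± 1.66 TPM. Cytosolic ribosomal protein genes had 3 of 78 members lower and 1 higher (1 and 0 adjusted over the list alone), and a camera adjusted p of 0.0441 in the lower direction, but adjusted p = 0.873 with an estimated correlation. RPL27 and RPL21 were among the lower genes and RPS9 was higher, but the RPL21 and RPS9 calls ended without 8 and 9 of the 12 libraries in turn (adjusted p up to 0.11 and 0.103). The direction of the list turned to higher with quantile normalization (adjusted p = 0.791) and without TOP2B-/- replicate 1 (adjusted p = 0.895), and its call also ended without WT replicate 1 or 2 or TOP2B-/- replicate 3 (adjusted p of 0.0615, 0.319 and 0.97). These are short transcripts, which the length score of TOP2B-/- replicates 2 and 4 favours. Without those 2 libraries all 8 lists still passed in the same direction, and 7 of them had more genes called, the T and NK cell markers as many. With an estimated correlation 0 of them passed without those libraries (adjusted p of 0.238 to 0.308). The genes higher were 17 of the p53 targets with 2 lower, 15 of the HLA list, 21 of the G1/S list, 13 of the homologous recombination list, 17 of the cholesterol list and 5 of the T and NK cell markers. The genes lower were 12 of the glycolysis list with 3 higher, and 49 of the ribosomal protein list. The count of all called genes rose as well in that setting. Replicates 1 and 3, which remain in it, favour long transcripts by their length scores. With the length score fitted instead, 14 ribosomal protein genes were higher and 21 lower. The p53 targets then had 15 higher and 2 lower, and the G1/S genes 18 and 0.

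The 16 other tested lists did not pass by camera. By fry, which does not compare a list with other genes, some of them passed, among them the carbonyl reduction list (fry adjusted p = 5.17e-05). The ribosomal protein list, which passed by camera, did not pass by fry (fry adjusted p = 0.79). Among pre-B and B cell identity genes 7 of 37 were higher and 5 lower (11 and 6 adjusted over the list alone; camera adjusted p = 0.964). VPREB1, part of the surrogate light chain, was higher (498 ± 8.53 to 672 ± 47.3 TPM), VPREB3 lower (289 ± 5.66 to 201 ± 13.5 TPM), LEF1 higher (324 ± 13.4 to 417 ± 16.9 TPM) and CD9 lower (533 ± 23.1 to 443 ± 8.85 TPM). Among genes of carbonyl reduction, anthracycline metabolism and drug efflux 5 of 16 were higher and 2 lower (7 and 3 adjusted over the list alone; adjusted p = 0.698). Besides CBR1 they included NQO1, a quinone reductase, from 4.83 ± 0.52 to 7.44 ± 0.42 TPM, AKR1A1 from 135 ± 3.33 to 156 ± 7.57 TPM and AKR7A2 from 20.8 ± 0.46 to 27.6 ± 3.29 TPM. The AKR1A1 and AKR7A2 calls ended with libraries centred on their median log ratio (adjusted p of 0.16 and 0.0584). Of the topoisomerase and repair genes 1 of 16 was higher and 2 were lower (1 and 2 adjusted over the list alone; adjusted p = 0.367). Of the non-homologous end joining genes 2 of 17 were higher and 1 lower (2 and 1; adjusted p = 0.906), and among the G2/M genes 4 of 28 were higher and 6 lower (4 and 6; adjusted p = 0.247). Interferon response genes were higher for 6 of 33 and lower for 1 (7 and 1; adjusted p = 0.0626, and 0.0472 without WT replicate 3, but adjusted p = 0.813 there with an estimated correlation). With the length score fitted the interferon list also passed (camera adjusted p = 0.028, but adjusted p = 0.112 with an estimated correlation).

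The cohesin, condensin and CTCF list had 5 of 24 genes higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.408, and 0.0289 without TOP2B-/- replicate 2, but adjusted p = 0.837 there with an estimated correlation). Counts for the other lists, again with those adjusted over the list alone after each, were 1 higher and 0 lower of 18 translocation partner genes (1 and 0; adjusted p = 0.438), 4 and 2 of 18 immediate early genes (4 and 2; adjusted p = 0.779), 1 and 0 of 15 glucocorticoid and retinoic acid response genes (1 and 0; adjusted p = 0.768) and 1 and 0 of 10 NF-kB targets (1 and 0; adjusted p = 0.711). They were 5 and 3 of 26 unfolded protein and amino acid stress genes (5 and 3; adjusted p = 0.408), 4 and 1 of 19 NRF2 and oxidative stress genes (4 and 1; adjusted p = 0.438) and 5 and 0 of 13 mitochondrial-encoded genes (5 and 1; adjusted p = 0.408). Myeloid markers had 2 of 7 higher and 1 lower (2 and 1; adjusted p = 0.779), and fibroblast and epithelial markers 0 of 5 in either direction (0 and 0; adjusted p = 0.85). The median, mean and test of a list differed in sign for the topoisomerase, carbonyl reduction, glucocorticoid, and fibroblast and epithelial lists, and the immediate early genes turned to lower with quantile normalization. Without TOP2B-/- replicates 2 and 4 the genes higher were 23 of the pre-B list with 6 lower, 15 of the interferon list with 1 lower and 15 of the cohesin list with 0 lower, and the cohesin list passed (adjusted p = 0.00839, but adjusted p = 0.615 with an estimated correlation). With the length score fitted instead, these 3 lists had 15 higher and 9 lower, 12 and 3, and 10 and 2. The other 4 lists had fewer than 5 tested genes, and of these 1 of 4 HOX, MEIS and PBX genes was higher, while 0 of 3 erythroid and megakaryocyte markers, 0 of 3 neuronal genes and 0 of 1 clustered protocadherin passed by limma.

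**Figure D3:**
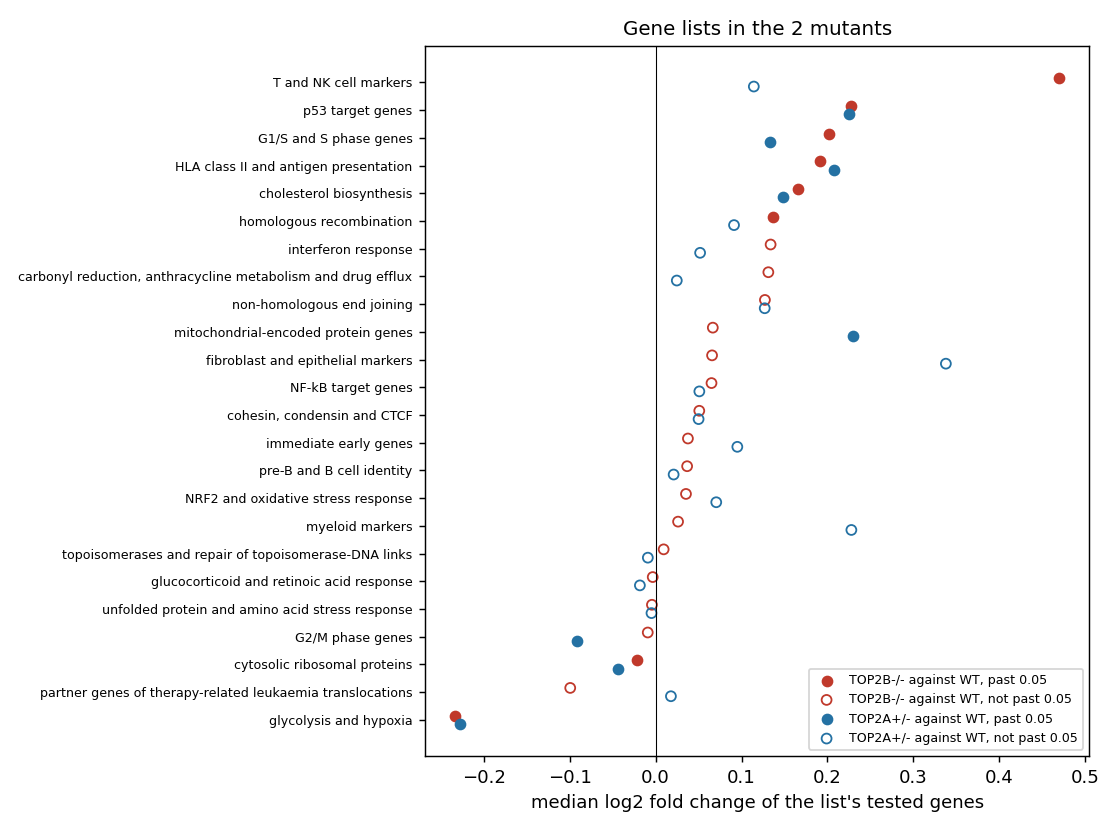
Median log2 fold change of the tested members of each of 24 gene lists, TOP2B-/- (red) and TOP2A+/- (blue) against WT. Filled circles passed the camera threshold of 0.05 with the preset correlation, and the glycolysis and hypoxia list lies lowest in both, at -0.23.

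The comparison of TOP2A+/- with WT asked the same of the loss of 1 copy of TOP2A. SPP1 had the largest increase, from 21.7 ± 0.81 to 76.2 ± 5.27 TPM (log2 fold change 1.76 ± 0.07 SE, adjusted p = 5.45e-08), the opposite of its change in TOP2B-/-. ADAMTS9, a secreted metalloprotease, rose from 2.29 ± 0.46 to 8.06 ± 0.76 TPM, the lectin receptor gene CLEC12B from 2.83 ± 0.18 to 9.10 ± 0.98 TPM and SPINK4 from 19.6 ± 1.38 to 52.8 ± 2.61 TPM. The largest decrease was that of S100A16, a calcium-binding protein gene, from 22.6 ± 1.82 to 0.10 ± 0.06 TPM (adjusted p = 4.34e-10). The metallothionein gene MT1H fell from 7.77 ± 1.42 to 0.66 ± 0.21 TPM, TMEM132A from 10.4 ± 1.35 to 1.69 ± 0.55 TPM, GSTK1, a glutathione transferase, from 19.5 ± 2.13 to 3.96 ± 0.35 TPM and MMADHC, a protein of cobalamin metabolism, from 73.2 ± 2.83 to 19.5 ± 0.43 TPM.

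Further increases were those of CLEC14A (14.4 ± 0.59 to 37.9 ± 1.09 TPM), CSMD1 (2.06 ± 0.21 to 6.30 ± 0.62 TPM), LYZ, which encodes lysozyme (2.70 ± 0.32 to 7.43 ± 0.99 TPM), the integrin gene ITGA6 (8.30 ± 0.81 to 19.8 ± 1.58 TPM), ABR (2.76 ± 0.29 to 7.19 ± 0.44 TPM) and IL2RG, the common gamma chain of cytokine receptors (9.32 ± 0.07 to 20.3 ± 1.24 TPM). Further decreases were those of NKD2 (5.98 ± 0.74 to 1.37 ± 0.32 TPM), XAF1 (14.4 ± 1.90 to 5.41 ± 0.86 TPM), ODF2L (33.3 ± 2.09 to 14.1 ± 2.04 TPM), SIKE1 (33.6 ± 2.03 to 15.5 ± 0.61 TPM) and MT1G (1070 ± 45.4 to 542 ± 23.3 TPM). Metallothionein genes are near-identical copies, so the separate levels of MT1H and MT1G are uncertain.

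In all, 1749 genes passed, 1165 higher and 584 lower (66.6% higher), and 60 of them changed at least 2-fold, 40 higher and 20 lower. All 4 libraries of each genotype lay apart for 26.3% of the tested genes, against 2.86% by chance. The split was 955 higher and 877 lower (52.1% higher) with libraries centred on their median log ratio, and 839 and 834 with quantile normalization. The count was 1161, 1147 and 1137 without WT replicate 1, WT replicate 2 or TOP2A+/- replicate 4, and 3167 in a fit of these 8 libraries alone. The main fit has 1 estimate of spread for all 3 genotypes, and the TOP2B-/- libraries vary most among themselves (r from 0.954). The counts of 2784 genes for TOP2B-/- and 1749 for TOP2A+/- therefore do not rank the sizes of the 2 effects.

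**Figure D4:**
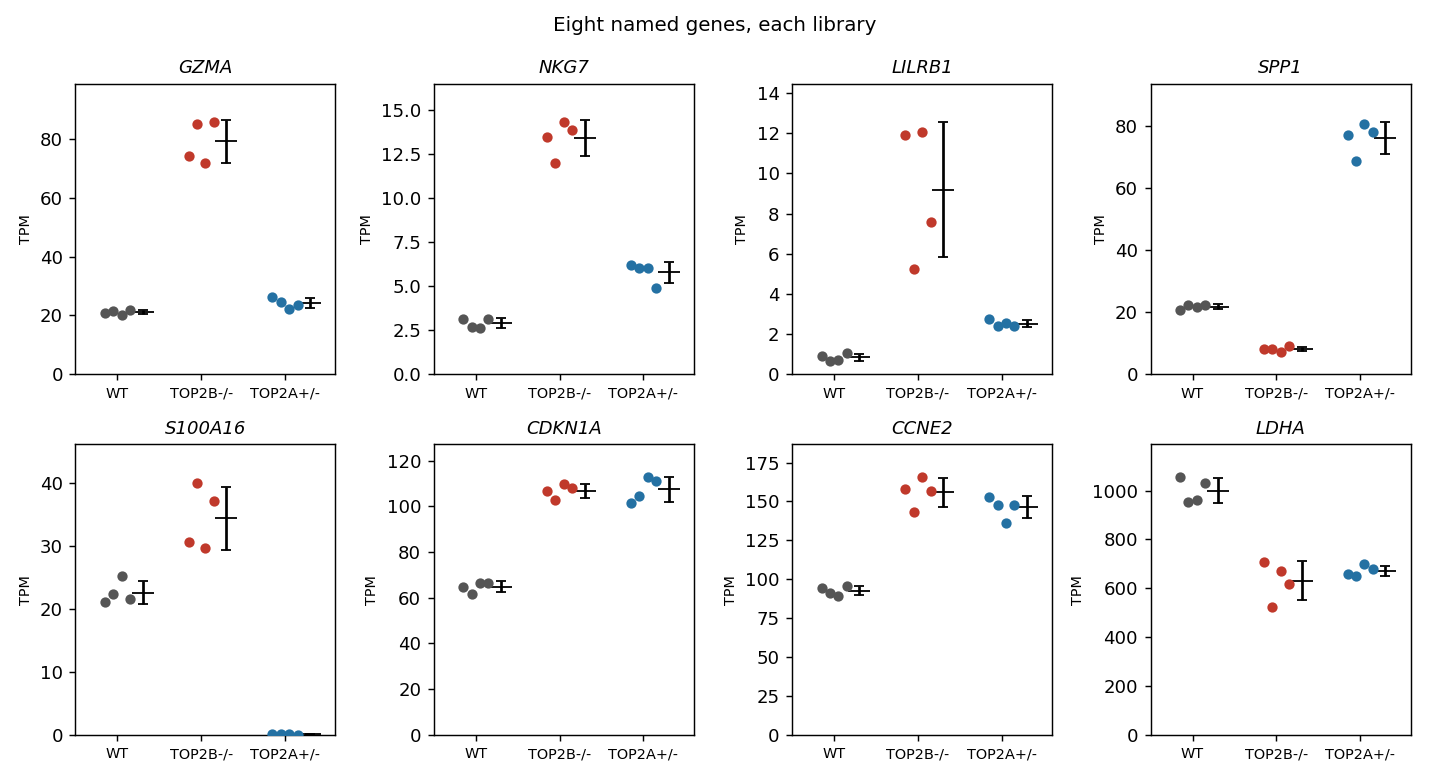
TPM of 8 named genes in each library (points) by genotype, with the mean and SD of 4 libraries (black). SPP1 lies above the WT libraries in TOP2A+/- and below them in TOP2B-/-, and S100A16 lies near 0 in TOP2A+/-.

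In TOP2A+/- the p53 target list had 9 of 26 members higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.000319, but adjusted p = 0.0528 with an estimated correlation). CDKN1A rose to 108 ± 5.39 TPM, DDB2 to 44.9 ± 0.65 TPM, ZMAT3 from 9.93 ± 0.70 to 16.1 ± 0.98 TPM and TP53INP1 from 3.59 ± 0.20 to 6.14 ± 0.29 TPM. HLA class II and antigen presentation genes were higher for 10 of 25 members and lower for 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000648, but adjusted p = 0.0528 with an estimated correlation). HLA-DRA was at 628 ± 3.88 TPM, HLA-DRB1 at 61.6 ± 1.54 TPM and HLA-DMA at 59.9 ± 1.80 TPM. B2M, the invariant chain of class I, rose from 3433 ± 80.2 to 4237 ± 110 TPM, which did not pass with libraries centred on their median log ratio (adjusted p = 0.0977). G1/S and S phase genes were higher for 6 of 27 and lower for 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.000559, but adjusted p = 0.296 with an estimated correlation). CCNE2 was at 146 ± 7.06 TPM, RRM2 at 400 ± 7.61 TPM and CCNE1 at 30.3 ± 1.16 TPM. RFC2 had 76.0 ± 1.18 TPM against 68.2 ± 2.23 TPM in WT, and its call ended without TOP2A+/- replicate 4 or WT replicate 2 (adjusted p of 0.053 and 0.0507).

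G2/M genes were lower for 6 of 28 members and higher for 0 (8 and 0 adjusted over the list alone; camera adjusted p = 1.4e-05, but adjusted p = 0.296 with an estimated correlation). CCNB1 fell from 177 ± 2.38 to 150 ± 3.03 TPM, CCNA2 from 119 ± 1.48 to 106 ± 2.22 TPM, the mitotic kinase gene AURKA from 62.2 ± 2.81 to 49.9 ± 1.74 TPM and CDC20, an activator of the anaphase-promoting complex, from 101 ± 3.86 to 84.4 ± 4.83 TPM. Glycolysis and hypoxia genes fell for 14 of 25 members and rose for 0 (17 and 0 adjusted over the list alone; camera adjusted p = 1.2e-14, but adjusted p = 0.0528 with an estimated correlation). BNIP3 was at 34.6 ± 2.26 TPM, ENO1 at 798 ± 26.7 TPM, P4HA1 from 34.7 ± 1.65 to 26.3 ± 1.18 TPM and ALDOA, aldolase, from 598 ± 6.37 to 511 ± 18.8 TPM. Ribosomal protein genes were lower for 3 of 78 members and higher for 0 (2 and 0 adjusted over the list alone; camera adjusted p = 0.000229, but adjusted p = 0.837 with an estimated correlation and 0.859 with quantile normalization). RPL14 and RPS26 were among the lower genes. The RPS26 call ended without WT replicate 2 or 3 or TOP2A+/- replicate 1, 2 or 4 (adjusted p of 0.0519 to 0.082).

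Cholesterol biosynthesis genes were higher for 5 of 22 members and lower for 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00662, but adjusted p = 0.342 with an estimated correlation). SQLE, squalene epoxidase, rose from 37.1 ± 1.57 to 47.5 ± 1.82 TPM, IDI1 to 222 ± 1.91 TPM, TM7SF2 from 12.9 ± 0.50 to 17.0 ± 1.498 TPM and SC5D to 32.4 ± 0.69 TPM. The IDI1 call ended with libraries centred on their median log ratio (adjusted p = 0.0744) and that of TM7SF2 with quantile normalization (adjusted p = 0.0956). Mitochondrial-encoded genes were higher for 7 of 13 and lower for 0 (10 and 0 adjusted over the list alone; camera adjusted p = 6.06e-05, but adjusted p = 0.122 with an estimated correlation). MT-CYB rose from 3040.2 ± 163 to 3807 ± 124 TPM, MT-CO1 from 9062 ± 265 to 10621 ± 101 TPM, MT-CO2 from 13234 ± 354 to 16040 ± 252 TPM and MT-ND2 from 3088 ± 164 to 3634 ± 148 TPM. The last 3 did not pass with libraries centred on their median log ratio (adjusted p of 0.135, 0.138 and 0.236). The mitochondrial share of TPM was 9.57% ± 0.22 in WT, 10.2% ± 0.37 in TOP2B-/- and 10.9% ± 0.16 in TOP2A+/-.

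Of the lists that did not pass by camera, pre-B and B cell identity had 5 of 37 genes higher and 4 lower (6 and 4 adjusted over the list alone; adjusted p = 0.377). VPREB3 fell to 165 ± 5.94 TPM, DNTT, the terminal transferase of immature lymphocytes, from 424 ± 10.7 to 306 ± 5.40 TPM, TCF3 from 178 ± 5.15 to 147 ± 3.62 TPM and CD9 to 434 ± 14.4 TPM. The test of this list pointed lower and its median higher, and with quantile normalization the test pointed higher. Carbonyl reduction, anthracycline metabolism and drug efflux genes were higher for 5 of 16 and lower for 2 (5 and 3 adjusted over the list alone; camera adjusted p = 0.75, but fry adjusted p = 0.00125). NQO1 was at 8.72 ± 0.35 TPM, CBR4 from 18.8 ± 0.45 to 14.5 ± 1.02 TPM and DHRS7 from 4.89 ± 0.58 to 3.38 ± 0.20 TPM. The T and NK cell markers had 1 of 8 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.32). Homologous recombination genes had 3 of 26 higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.147), and interferon response genes 3 of 33 in each direction (4 and 3 adjusted over the list alone; adjusted p = 0.875). With quantile normalization homologous recombination and NRF2 genes passed as higher (adjusted p of 0.0229 and 0.0267, but adjusted p of 0.135 and 0.25 with an estimated correlation).

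Many genes changed in the same direction in both mutants. Ranked by the smaller of their 2 log2 fold changes, CSMD1, CLEC14A, NPY, S100A10 and ZNF93 had the largest shared increases. NPY, which encodes neuropeptide Y, rose from 11.3 ± 0.73 TPM to 26.9 ± 5.32 TPM in TOP2B-/- and 23.2 ± 2.66 TPM in TOP2A+/-, and S100A10 from 7.22 ± 0.87 to 20.03 ± 5.31 and 14.8 ± 0.78 TPM. CLEC14A was at 32.6 ± 5.63 TPM, CSMD1 at 6.30 ± 1.00 TPM and ZNF93 at 21.1 ± 4.36 TPM in TOP2B-/-. By the same ranking TPCN1, BNIP3, PIF1, MT1G and P2RX5 had the largest shared decreases. PIF1, a DNA helicase, fell from 49.6 ± 2.73 to 28.9 ± 4.52 TPM in TOP2B-/- and 31.1 ± 3.26 TPM in TOP2A+/-, and P2RX5 from 5.84 ± 0.55 to 3.54 ± 0.30 and 3.49 ± 0.13 TPM. TPCN1 fell from 9.48 ± 1.63 to 3.66 ± 1.54 and 5.10 ± 0.76 TPM, and its TOP2A+/- call (adjusted p = 0.043) ended without 8 of the 12 libraries in turn (adjusted p of 0.0566 to 0.115).

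In all, 993 genes were called in the same direction in both mutants, 690 higher and 303 lower, and 77 in opposite directions. Independent lists of these sizes would share 149.5 higher and 36.8 lower genes. In 100 simulations of unchanged groups against the same WT libraries 0.02 genes were shared on average and at most 1. The simulated groups held no changed genes, so hardly any calls could be shared. Their count does not show how far shared controls make 2 real lists of calls coincide. With the WT libraries split 2 and 2, so that no control was shared, 379 to 423 genes were called in the same direction. The correlation of log2 fold changes across genes was 0.48 and that of simulated unchanged groups 0.50, because shared controls alone correlate the comparisons. The covariance was 0.0483 against 0.0283 simulated, a difference of 0.0201. The simulated spread was pooled over all 3 genotypes, and the TOP2B-/- libraries vary most among themselves. With the WT libraries split, and so no control shared, the correlation was 0.185 to 0.23 and the covariance 0.0261 on average. The shared count was 656 and 648 without WT replicate 1 or 2, and 1530 without TOP2B-/- replicate 2.

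**Figure D5:**
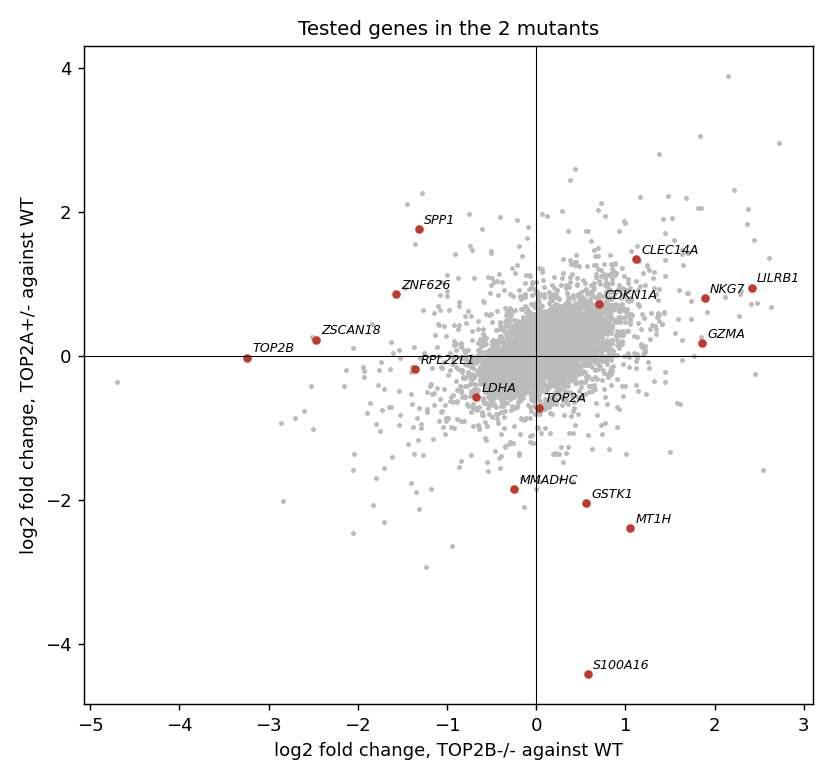
Log2 fold change (log2(TPM + 1) scale) of the 14555 tested genes in TOP2B-/- (horizontal) and TOP2A+/- (vertical) against WT, each grey point a gene, with named genes in red. CDKN1A and CLEC14A are higher and LDHA is lower in both, and SPP1 is lower in TOP2B-/- and higher in TOP2A+/-.

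Comparing the mutants directly, 1521 genes differed, 896 higher and 625 lower in TOP2B-/- than in TOP2A+/-, and 129 of them at least 2-fold. TOP2B and CBR1 were among the 5 largest differences in the lower direction. S100A16 had 34.4 ± 4.96 TPM in TOP2B-/- against 0.10 ± 0.06 TPM in TOP2A+/-, MT1H 17.1 ± 1.78 against 0.66 ± 0.21 TPM, GSTK1 29.1 ± 0.91 against 3.96 ± 0.35 TPM, TMEM132A 9.51 ± 2.36 against 1.69 ± 0.55 TPM and LILRA2 6.74 ± 1.32 against 1.37 ± 0.14 TPM. SPP1 had 8.17 ± 0.68 against 76.2 ± 5.27 TPM (log2 fold change -3.08 ± 0.07 SE, adjusted p = 2.94e-10), ZSCAN18 0.42 ± 0.27 against 8.15 ± 1.02 TPM and ZNF626 1.05 ± 0.23 against 10.1 ± 1.71 TPM. A fit of these 8 libraries alone called 903 genes, and 2184 of the 14555 tested genes had all 4 libraries of each mutant apart, against 2.86% by chance.

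T and NK cell markers were higher in TOP2B-/- than in TOP2A+/- for 5 of 8 members and lower for 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00046, but adjusted p = 0.275 with an estimated correlation). GZMA had 24.2 ± 1.77 TPM, NKG7 5.79 ± 0.58 TPM, LCK 9.50 ± 0.99 TPM and ZAP70 29.2 ± 2.997 TPM in TOP2A+/-, and the ZAP70 call ended without 10 of the 12 libraries in turn, with the highest adjusted p of 0.108 without TOP2A+/- replicate 2. Interferon response genes were higher for 6 of 33 and lower for 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.031, but adjusted p = 0.803 with an estimated correlation and 0.0682 without TOP2B-/- replicate 3). CMPK2 was at 7.94 ± 0.21 against 3.77 ± 0.35 TPM, MX1 at 13.9 ± 3.12 against 6.14 ± 0.63 TPM, XAF1 at 19.1 ± 5.20 against 5.41 ± 0.86 TPM and IFITM2 at 416 ± 15.8 against 348 ± 11.6 TPM. G2/M genes were higher for 5 of 28 and lower for 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00797, but adjusted p = 0.803 with an estimated correlation). NEK2 was at 37.7 ± 0.90 against 32.4 ± 0.86 TPM and ANLN at 44.1 ± 1.84 against 36.7 ± 1.07 TPM. Both these calls and that of IFITM2 ended with libraries centred on their median log ratio (adjusted p of 0.0506, 0.0533 and 0.059). AURKB and CDK1, also of the G2/M list, lost their calls without 2 and 3 of the 12 libraries in turn (adjusted p up to 0.0616 and 0.0813). Mitochondrial-encoded genes were lower for 4 of 13 and higher for 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00797, but adjusted p = 0.803 with an estimated correlation). MT-ND5 was at 1401 ± 350 against 2150 ± 131 TPM. Its call ended without TOP2B-/- replicate 4 or TOP2A+/- replicate 4 (adjusted p of 0.0512 and 0.0518). The calls of MT-ND1, MT-ND2 and MT-CYB, the other 3, ended without 9, 5 and 4 of the 12 libraries in turn (adjusted p up to 0.112, 0.0839 and 0.0771).

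Genes of the B cell lineage also differed between the mutants. DNTT had 425 ± 8.49 TPM in TOP2B-/- against 306 ± 5.40 TPM in TOP2A+/-, LEF1 417 ± 16.9 against 322 ± 14.8 TPM, IRF8 5.26 ± 0.86 against 1.92 ± 0.28 TPM and CD34, a progenitor marker, 0.21 ± 0.06 against 1.67 ± 0.19 TPM. The whole list had 7 of 37 genes higher and 3 lower and did not pass (10 and 5 adjusted over the list alone; adjusted p = 0.356). It passed as higher without TOP2B-/- replicates 2 and 4, with 19 genes higher and 4 lower (adjusted p = 0.0136, but adjusted p = 0.549 with an estimated correlation). Of the p53 targets 6 of 26 were higher in TOP2B-/- and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.21), with the death receptor gene FAS at 13.1 ± 1.46 against 8.45 ± 0.47 TPM and PHLDA3 at 6.64 ± 0.67 against 4.46 ± 0.32 TPM. Without TOP2B-/- replicates 2 and 4, 7 lists passed in place of 4, and 0 with an estimated correlation. The genes higher were then 17 of the G2/M list with 0 lower and 12 of the cohesin list with 1 lower (5 and 0, and 0 and 1, with all libraries), and the cohesin list passed (adjusted p = 0.0119, but adjusted p = 0.549 with an estimated correlation). The ribosomal protein genes, which did not pass (5 of 78 higher and 3 lower; adjusted p = 0.489), changed direction with the libraries left out. They passed as higher without TOP2B-/- replicate 1 or 3 (adjusted p of 0.000857 and 0.00154), and as lower without replicate 2 (adjusted p = 0.00541) or without replicates 2 and 4 (28 lower and 5 higher; adjusted p = 5.75e-13). With an estimated correlation the list passed in 0 of these 4 settings (adjusted p of 0.502 to 0.878). With the length score fitted, 12 G2/M genes were higher and 1 lower, and 6 cohesin genes higher and 1 lower. The pre-B list then had 16 higher and 7 lower, and the ribosomal protein list 13 and 10.

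Type II topoisomerases are held to ease the transcription of long genes, so genes with a body over 100 kb were examined as a group. In TOP2B-/- 277 of 1990 such genes were higher and 87 lower, with a median log2 fold change of 0.04 against 0.02 for the 8951 other protein-coding genes. By permutation of the 8 libraries 27 of the 35 splits gave a difference as large, and camera gave p = 0.505. The difference of medians, 0.0202, was 0.0554 without TOP2B-/- replicate 2 (camera p = 0.0344, no permutation run) and 0.0922 without replicates 2 and 4 (camera p = 0.00173). With an estimated correlation camera gave p = 0.91 with all libraries, and p of 0.67 and 0.461 in these 2 alternatives, no permutation run. The difference was -0.0123 without replicate 1, in a genotype whose libraries differ in their content of long transcripts. With the length score fitted, camera gave p = 0.313, and p = 0.295 with an estimated correlation, no permutation run. In TOP2A+/- 160 were higher and 57 lower, with a median of 0.05 against 0.03. By permutation 12 of the 35 splits gave a difference as large, and camera gave p = 0.493. By chromosome, 0 of 23 chromosomes were shifted in TOP2B-/- by camera. In TOP2A+/- chromosome 15 was shifted downward, with 23 of 513 tested genes higher and 53 lower (camera adjusted p = 0.0246, but adjusted p = 1 with an estimated correlation).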

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

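The tests of CBR1, of the T and NK cell markers and of the shared changes were chosen only after these results were seen; the counts of other splits were set before the data were examined.

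In groups of 4 libraries, 381 groups of values were searched for a library far from its 3 companions, and 13 were found, where chance gives 19.05. There were 5 in TOP2B-/-, 4 in WT and 4 in TOP2A+/-. In TOP2B-/- they were ADAMTS9 in replicate 3 (3.36 TPM, the nearest other library 4.32), CBR3 in replicate 2 (4.24 TPM against 3.37), CCNE1 in replicate 1 (27.8 TPM against 31.0278), CD9 in replicate 1 (430.1 TPM against 447) and GPER1 in replicate 3 (1.68 TPM against 1.39). In WT they were ANLN in replicate 2 (38.02 TPM against 34.8), CSMD1 in replicate 4 (1.75 TPM against 2.12), SQLE in replicate 3 (34.8 TPM against 37.9) and TM7SF2 in replicate 1 (13.7 TPM against 12.7). In TOP2A+/- they were INSIG1 in replicate 2 (58.4 TPM against 53.5), NKG7 in replicate 4 (4.92 TPM against 6.004), TM7SF2 in replicate 4 (14.8 TPM against 17.5) and the share of TPM in the 10 most abundant transcripts in replicate 3 (11.46% against 11.3%). Groups without spread, such as CBR1 in TOP2B-/-, could not be flagged, so the number given by chance is too high. The search took each value alone and does not find a library that differs across many genes. TOP2B-/- replicate 2, with the lowest length score (-0.47), was flagged in 1 group. Transcripts matched to no gene were left out of the comparisons. Of 2910 such transcripts tested, 108 passed for TOP2B-/- against WT and 67 for TOP2A+/- against WT.

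Other splits of the 8 libraries of each comparison, 35 with the real one, were fitted in the same way. For TOP2B-/- against WT 1 split, the real one, gave as many as 2784 genes, and the highest other gave 2. For TOP2A+/- against WT it was again 1 split, with 1749 genes against 3, and between the mutants 1 split, with 1521 genes against 4. No other split came near these counts of genes, and 1 of 35 is the smallest share that this test can give. The other splits mix the genotypes and the libraries may be technical, so chance differences between cultures or clones were not tested. Chance assignment of the libraries is not excluded for the counts of gene lists. For TOP2B-/- 4 splits gave as many as the real 8 lists (highest other 9), for TOP2A+/- 3 splits gave as many as 8 (highest other 9), and between the mutants 8 splits gave as many as 4 (highest other 8). Nor is it excluded for genes over 100 kb, where 27 splits gave a difference of medians as large as 0.0202 in TOP2B-/- (highest other 0.0918) and 12 splits one as large as 0.0206 in TOP2A+/- (highest other 0.0433). For chromosomes in TOP2A+/- 6 splits gave at least the real 1 (highest other 2). In TOP2B-/- the real count was 0, which all 35 splits reach by construction (highest other 1), so this count says nothing about chance.

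CBR1 was listed at 0 in all 4 TOP2B-/- libraries. Low depth or poor RNA would leave other genes of that level at 0, but 0 of 1593 other protein-coding genes between 3 and 8 TPM in WT were at 0 in all 4 libraries. Loss of a segment reaching the neighbouring genes is argued against by SETD4, which stood at 88.5% of its WT mean (lowest library 62.2%, with a bound set at 60%). It is also argued against by CBR3, which did not fall (lowest library 126% of its WT mean). The call of CBR3 as higher ended in several alternatives. Assignment of CBR1 reads to its paralog CBR3 is argued against by the size of the CBR3 gain, 0.997 TPM against a CBR1 loss of 4.70 TPM, and CBR3 gained 2.06 TPM in TOP2A+/-, where CBR1 was not lost. A deletion limited to CBR1 in the TOP2B-/- cells stays open, as does an effect of TOP2B loss. The labels do not say whether more than 1 clone was sampled, so these may not be separable here.

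GZMA, NKG7 and other T and NK cell markers were higher in TOP2B-/-. T or NK cells in the cultures would bring their other abundant transcripts. CD3D, CD3E, CD2, GZMB, PRF1 and GNLY together gained 0.342 TPM, against a gain of 68.7 TPM for GZMA and NKG7, and CD3D and GZMB were listed at 0 in each TOP2B-/- library. Of the 27 genes of the list 8 were expressed enough to be tested, GZMA at 21.2 TPM in WT itself. Poor RNA in TOP2B-/- replicates 2 and 4 is argued against as the whole cause, since the list still passed without them (camera adjusted p = 0.00851, but adjusted p = 0.308 with an estimated correlation). An effect of TOP2B loss on these genes may underlie the pattern, as may another property of the edited cells. In the main fit of all libraries the list did not pass by camera with an estimated correlation (adjusted p = 0.149).

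In both mutants 993 genes changed in the same direction. Of 100 assignments of the 12 libraries to 3 groups, 1, the real one, gave as many, and the highest other gave 535. The other assignments mix the genotypes. The count therefore ties the sharing to the genotype groups but does not test the overlap of 2 real lists of calls. The WT libraries that both comparisons share are argued against as the whole cause. With 2 WT libraries for each mutant the shared calls were at least 7.41 times the number expected of independent calls. A state of the WT culture, or the handling that both edited lines went through, cannot be told apart from an effect of the topoisomerases, since 0 WT libraries were marked as handled like the edited lines. An effect common to both enzymes may be weighed only with such libraries.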

How the results depend on the processing

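Leaving out TOP2B-/- replicates 2 and 4 and fitting the length score as a covariate were chosen only after the results were seen, as was the estimated correlation within an alternative.

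For named genes, 3745 of 3910 values under the alternatives named with the methods kept their side of the threshold. Of the rest 161 lost the call, 4 gained it and 0 reversed. Direction was compared only where the main or the alternative value was called, so an uncalled result may have changed sign. Of 175 called results 140 were called in all of these alternatives. TOP2B in TOP2B-/- (log2 fold change -3.43 to -2.98 leaving out each library), CBR1 in TOP2B-/-, and TOP2A (-0.73 to -0.69) and CBR3 (0.61 to 0.73) in TOP2A+/- kept their calls in all alternatives run. The filter on a mean of 5 TPM removes CBR1 and CBR3, so it gave no value for them.

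In the order TOP2B-/- against WT, TOP2A+/- against WT and TOP2B-/- against TOP2A+/-, the gene counts of 2784, 1749 and 1521 became 6264, 3939 and 4137 with library weights, which set TOP2B-/- replicate 2 at 0.0938. They were 106, 60 and 129 with a fold of at least 2, by construction. Leaving out each library gave 2130 to 3986, 1137 to 2620 and 1033 to 2179. Fits of the 2 groups alone gave 3167 genes for TOP2A+/- against WT and 903 between the mutants. Without TOP2B-/- replicates 2 and 4 the counts were 5654, 3452 and 3841, and with the length score 5787, 4370 and 3899. The shared calls, 993, were 8 with a fold of at least 2, 379 to 423 with WT split, 648 to 1530 leaving out each library, 2022 without TOP2B-/- replicates 2 and 4 and 2702 with the length score.

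The gene lists passing, 8, 8 and 4, were 2, 0 and 0 with an estimated correlation (the p53 and HLA lists of TOP2B-/-, which had an adjusted p of 0.112 once the length score was also fitted and 0.238 without TOP2B-/- replicates 2 and 4), and 14 and 14 for the mutants against WT with fry, which does not compare a list with other genes. Between the mutants 7 passed without TOP2B-/- replicates 2 and 4, and 0 of them with an estimated correlation. With an estimated correlation after quantile normalization 5, 5 and 1 passed. These counts also changed when single libraries were left out. For TOP2B-/- against WT 0 passed without TOP2B-/- replicate 1 or 2 or TOP2A+/- replicate 1 or 2. For TOP2A+/- against WT 4 passed without WT replicate 2 and 1 without TOP2A+/- replicate 1. The shifted chromosome in TOP2A+/- became 0 with an estimated correlation.

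CBR3 in TOP2B-/- lost its call with a log2 fold change of 0.36 without a filter, in the 2 groups alone and with its highest transcript alone, 0.32 centred, 0.24 with quantile normalization and 0.28 without TOP2B-/- replicates 2 and 4. It ranged from 0.29 to 0.42 leaving out each library. The difference of medians for genes over 100 kb in TOP2B-/- ranged from -0.0123 to 0.0554 leaving out each library, and was 0.0922 without replicates 2 and 4. Except where construction shows it, the cause was not tested. TPM hold no depth, so the depth behind weak genes is unknown.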

Other observations

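The tests of neighbouring genes and of zinc finger genes were chosen only after the named genes were seen, with predictions written before the tests were run. The zinc finger values without TOP2B-/- replicates 2 and 4, and the count of neighbouring pairs without GPR146 and GPER1, were chosen after seeing the data.

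ZSCAN18, ZNF43 and ZNF626 were among the largest decreases in TOP2B-/-, so zinc finger genes of chromosome 19 were tested as a set. The set took symbols that start with ZNF and so leaves out ZSCAN18. The hypothesis of a fall was not borne out, and the set pointed higher. Of 192 tested genes 52 were higher and 5 lower in TOP2B-/-, with a median log2 fold change of 0.20. Camera with the preset correlation called the set higher (p = 1.16e-05, and 4.75e-07 without TOP2B-/- replicates 2 and 4, no permutation run), but not with an estimated correlation (p = 0.426, no permutation run). In TOP2A+/- 41 were higher and 0 lower, with a median of 0.22 (p = 6.39e-09 preset and 0.299 estimated, no permutation run). The fall of ZNF43 and ZNF626 was therefore not shared by the set, which does not speak to genes named like ZSCAN18.

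GPR146 and GPER1, which both fell in TOP2B-/- (log2 fold changes of -1.76 and -1.54), lie 22.9 kb apart on chromosome 7. This raised the hypothesis that changed genes lie beside each other more often than chance. Pairs were tested protein-coding genes next to each other in gene order, so untested genes can lie between them. Pairs that overlap or whose symbols start alike were left out. Among 8796 such pairs, 24 changed in the same direction by at least 0.5 (log2) in TOP2B-/-. In 10000 shuffles the mean was 16.2 and the highest 32 (permutation p = 0.0356). The 24 pairs include the one that prompted the test. Without GPR146 and GPER1 there were 23 pairs, against a mean of 16.2 and a highest of 34 (permutation p = 0.0609), so an excess in TOP2B-/- is not established. In TOP2A+/- there were 11 pairs, against a mean of 4.35 and a highest of 13 (permutation p = 0.0045). RASIP1 and IZUMO1, a pair chosen after its values were seen, lie 0.131 kb apart and rose in both mutants. The gaps of the TOP2A+/- pairs ran from 0.131 to 2051 kb, so not all of them are close neighbours. Shuffles do not keep the level of a gene or its neighbourhood, so regions of expressed genes could give the same excess. Whether changes reach across neighbouring genes cannot be told from this count.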
